A study of Mus musculus with 10 samples.

How the data were processed

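Gene expression was measured with 2-colour spotted arrays in the paraventricular nucleus of the hypothalamus (PVN) of mice. The arrays compared animals kept from their mothers for 24 h with animals that were not. Per the labels' protocols, frozen brains of 6 animals per group were sectioned at 100 µm, and the nucleus was taken with a corer of 1 mm. Punches of 2 animals were joined, which gave 3 samples per group. RNA was extracted with Trizol and amplified in 1 round, and equal amounts of the amplified RNA were joined into 1 pool of 40 µg per group. One part of each pool was labelled with Cy3 and the other with Cy5. The 2 pools were hybridised together on 10 arrays, 5 with the separated pool in Cy5 and 5 with it in Cy3. The arrays are therefore technical repeats of 1 comparison, and they carry no information on the spread between animals or litters. No p-value for an effect of separation on animals was computed, and p-values from limma below concern array error between these pools. Litter identity, age and sex of the animals were not given in the sources used here.

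Each array file held 24192 spots in 48 blocks of 504. Spot intensity was deposited on a linear scale and, per the file headers, was quantified with QuantArray by a fixed circle, with no background subtraction and no crosstalk correction. The other scanner columns used here, the local background and its SD in each channel, were deposited on the same linear scale, per the file headers. The series value table held log2 ratios deposited by the authors for 19025 spots per array. Its direction and scale were found by setting each column against the same array's spot intensities. Under the dye assignment used here, all 10 columns ran as non-separated over separated, with correlations of -0.94 to -0.90 against separated over non-separated. Were each array's title to name the pool in Cy5, the columns would run as separated over non-separated. Their medians lay between 0.0011 and 0.0094, and their median absolute deviation was 0.526 on every array, so they had been scaled between arrays. The normalization that the authors used to make these log2 values is not given in the sources used here. That table served only as an alternative.

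Spots carried descriptive gene names and no symbols. Symbols were given by hand to 521 names, some of them old aliases, and these were not checked against clone sequences. RIKEN clones, expressed sequences, DNA segments and accessions were matched to the RefSeq gene table of assembly GRCm38.p6. This named 6002 of 6275 RIKEN clones, 597 of 633 expressed sequences, 261 of 318 DNA segments and 5 of 764 accessions. A spot kept the file's own name where no symbol was given. In all, 16275 spots were tied to 1 gene, covering 11417 genes, of which 3484 had more than 1 spot. A further 1374 control spots, 1170 of them empty, were left out after background correction, and 5418 spots had no gene name.

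Background was corrected with normexp (offset 50) and ratios were normalised within each array by global loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Every ratio was turned to separated over non-separated. For this, arrays titled as non-separated animals were taken to carry the separated pool in Cy5. Arrays titled as separated animals were taken to carry it in the other dye. If the titles instead name the pool in Cy5, every direction given here would reverse. A gene's value was the average of the 2 orientation means, and its SD was taken over the 10 arrays, so it includes the dye effect. Each gene was read from its brightest spot. A spot counted as detected where either channel exceeded its local background by 2 SD of that background on at least 8 of 10 arrays. Local background was 0 for 91.6 to 100% of spots, so all 22818 spots that were not controls passed, and the rule removed nothing. A detection rule based on empty spots was therefore added after seeing the data. A gene was called higher or lower when it was detected, at least 1.5-fold different and of the same sign on every array with a value. These rules, the 23 gene lists with 737 symbols, the alternatives and the rule for named genes were fixed before the data were examined.

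The genes named are the 15 largest calls in each direction and the called members of each list, at most 8 by size. Every detected member of the renin-angiotensin and sex-chromosome lists is named too, with Crh, Avp, Oxt, Trh, Nr3c1 and Crhr1. With under 10 genes called in a direction, the 10 largest of one sign on every array are named, and those under the size limit are given as values. Other list members given below, none of them called, fall outside this rule. Their choice was not fixed beforehand, and they serve as examples only. Results for 3 genes are not reported here, though they remain in all counts and list medians; the search for arrays that stand apart left them out. For each list, the median of its detected members was set among 10000 random lists of the same size matched on intensity in 20 bins. That percentile describes these 2 pools and is not a test. Lists covered the renin-angiotensin system, stress axis, glucocorticoid-responsive genes, immediate early genes, feeding peptides, fasting metabolism, cholesterol synthesis and sex chromosomes. Further lists marked myelin, astrocytes, microglia, vessels, blood, choroid plexus, meninges and neighbouring brain regions. The others covered amino acid and monoamine transmission, proliferation, clock genes, heat shock, oxidative phosphorylation and ribosomal proteins. Of their symbols, 593 were detected.

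The procedure was tested on simulated arrays with 200 changed genes among 11417, built from the real brightness, dye effects and spread of this comparison. It called 31.3% of 67 genes changed 1.5-fold, 64.2% of 67 changed 2-fold and 93.9% of 66 changed 3-fold. Of 11217 unchanged genes, 2 were called. Absence from the calls is thus weak evidence for no difference at 1.5-fold and moderate at 2-fold. The simulated noise was independent between arrays and genes, and no effect of scan day was put in. The 2 false calls therefore do not cover calls that scan day could cause.

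Alternatives covered background correction, normalization, detection, fold limit, sign rule, summary over arrays and over spots, each dye orientation alone, each array left out, and the authors' log2 values. limma over the 10 arrays with a dye term was run as a test of array error between these pools, with and without the replicate number as a block. A spot median could not replace the spot mean, since 1 intensity per spot and channel was read. No spot carried a filter mark, so keeping such spots moved nothing. Calls, list medians and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

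The scans were made on 2 days, 1 dye orientation per day, so dye orientation and scan day cannot be told apart. A dye effect common to both days cancels in the average of the 2 orientations, but a scan day effect on the ratio does not. Every call, list median and limma p-value for the difference between the pools may therefore hold a scan day effect. The number of arrays limits precision only for the array error, since each group was 1 pool.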

Results

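Separation of pups from the mother for 24 h was set against no separation in the paraventricular nucleus (PVN), the hypothalamic nucleus whose neurons drive pituitary stress hormone release. Litters had been allotted to the conditions at random. The series title names the renin-angiotensin system, the pathway that makes angiotensin from angiotensinogen, so its members are given one by one. For each group, RNA of 6 animals formed 1 pool, and the 2 pools met on 10 arrays, 5 per dye orientation. Median spot intensity ranged from 286 to 529 in Cy5 and from 436 to 1011 in Cy3. Values are log2 ratios of separated over non-separated with the SD over 10 arrays (n = 10 technical repeats), and there were no replicate pools.

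Transcripts of astrocytes and angiotensinogen were among the largest differences between the pools. Gjb6, which encodes the astrocyte gap junction protein connexin 30, fell by 1.22 ± 0.40, and Agt, the angiotensin precursor, fell by 0.91 ± 0.64. Aldoc, a glycolytic enzyme of astrocytes, fell by 0.73 ± 0.35. The brightest spot of Rundc3a, which encodes a binding partner of the GTPase Rap2, lay at -1.35 ± 0.40, but 1 of its 3 spots was called and their median was -0.19. In the other direction, a spot for Tsix, the antisense partner of the X-inactivation RNA Xist, rose by 1.03 ± 0.25. Hmgcs1, an early enzyme of cholesterol synthesis, rose by 0.67 ± 0.20.

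In total, 7 genes were higher and 22 lower in the separated pool by at least 1.5-fold with the same sign on every array. These and all other directions rest on the dye assignment used here. If the array titles name the pool in Cy5, 22 would be higher and 7 lower. The planned detection rule removed no spot. Under a stricter one set on empty spots and chosen after the data were seen, 1692 genes remained, with 3 higher (Tsix, Hmgcs1 and Srsf11) and 4 lower, among them Aldoc and Meg3. Agt, Gjb6, Rundc3a and Ddx3y did not pass that detection rule. Folds ran from 1.50 to 2.55 among the lower genes and from 1.50 to 2.04 among the higher ones. The Y-linked RNA helicase gene Ddx3y fell by 0.93 ± 0.49. Olah, a thioesterase of fatty acid synthesis, fell by 0.77 ± 0.24, and Coasy, an enzyme of coenzyme A synthesis, by 0.72 ± 0.56. A spot named sulfide quinone reductase-like, a mitochondrial enzyme, lay at -0.75 ± 0.35. Meg3, an imprinted non-coding RNA, fell by 0.71 ± 0.20. Map4k4 and homeodomain interacting protein kinase 3, both protein kinases, lay at -0.67 ± 0.38 and -0.67 ± 0.41, the latter from a dim spot. The brightest spot of Dennd11 lay at -0.77 ± 0.52, but 1 of its 5 spots was called and their median was -0.07. Lysmd1 fell by 0.70 ± 0.45. A spot named interleukin 25 lay at -0.77 ± 0.25, under an old name that does not settle which protein it encodes. The metallothionein gene Mt1, whose product binds metals, fell by 0.61 ± 0.31. Further genes were lower by the same rule. Without replicate 1 of the arrays with the separated pool in Cy3, 16 genes in place of 7 were higher.

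Besides Tsix and Hmgcs1, the higher genes were Srsf11, a splicing factor gene, at 0.60 ± 0.35 and Rabl6, a GTPase-like gene, at 0.59 ± 0.35. Upstream transcription factor 1, at 0.61 ± 0.47, and the acetyltransferase gene Naa60, at 0.76 ± 0.58, were among the dimmer spots. Prolactin-like protein M, a member of the prolactin family, was dim as well, at 0.86 ± 0.69. Under the size limit but above 0 on every array were Tcf7l2, a transcription factor of Wnt signalling, at 0.56 ± 0.35, microsomal epoxide hydrolase 1 at 0.55 ± 0.53 and Foxred2 at 0.52 ± 0.29.

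Several genes had spots that differed. The other spots of Rundc3a reached 0.12, those of Dennd11 0.23 and those of Srsf11 -0.24, and the second spot of Naa60 lay at -0.14. The weakest spots of Coasy, Lysmd1, Ddx3y, Meg3 and Rabl6 lay near 0, at -0.08, -0.10, -0.06, -0.05 and 0.02. Of these genes' spots, 1 of 2, 1 of 2, 2 of 3, 1 of 6 and 1 of 3 were called. The 4 spots of Aldoc lay between -0.87 and -0.19, and the weaker spot of Hmgcs1 at 0.40. At any size, 48 genes were above 0 and 131 below 0 on all 10 arrays, where random signs would give 22.3 in all. Across genes, which are not independent replicates, the 2 orientation means correlated at -0.17. Dye effects were frequent, with 1252 of 22818 spots at an adjusted p under 0.05 for the dye term in limma, against 83 for the difference between the 2 pools, a p-value of array error only. Read over all its spots, a gene was called higher in 3 cases and lower in 13.

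**Figure D1:**
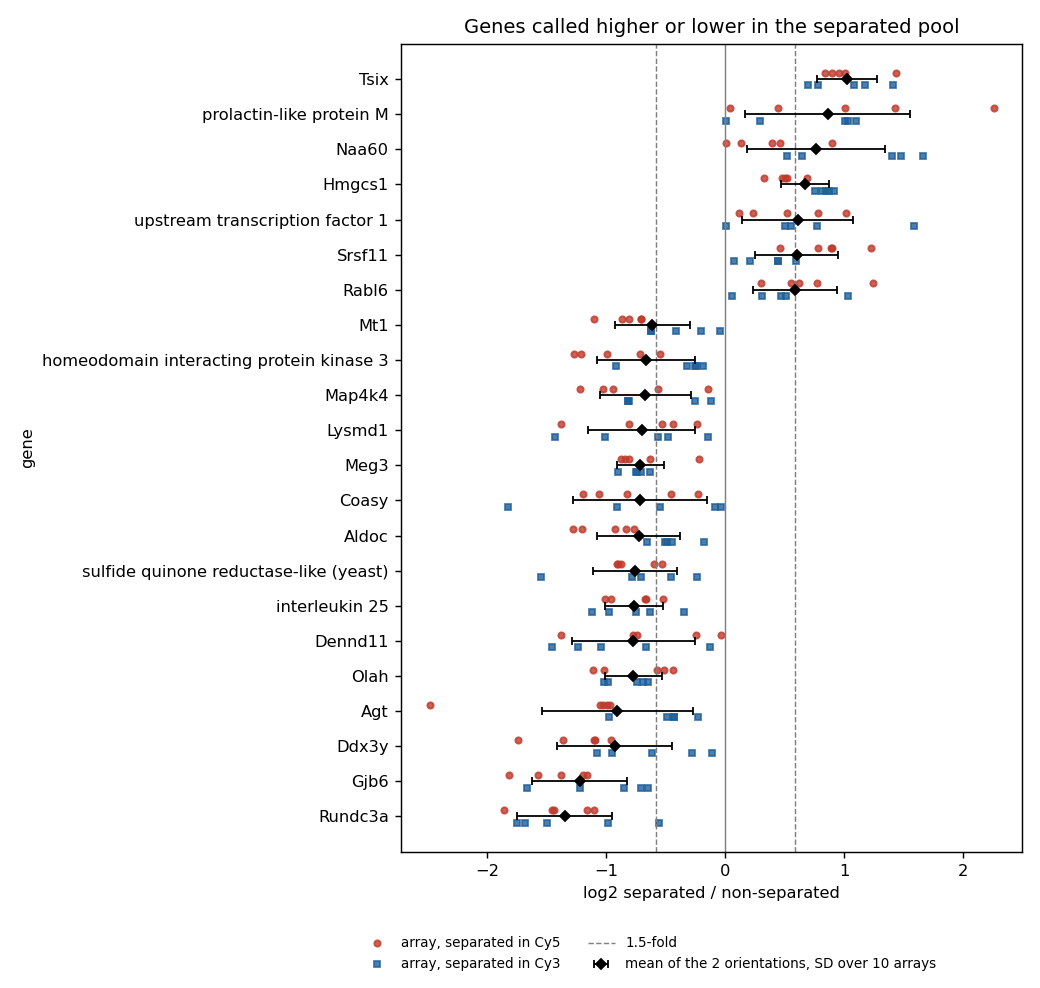
Log2 ratio of separated over non-separated (horizontal axis) for genes called higher or lower that are named here (vertical axis). Circles are arrays with the separated pool in Cy5, squares those with it in Cy3, diamonds the mean with its SD over 10 arrays, and dashed lines 1.5-fold. Each gene lies on one side of 0 on all 10 arrays, from Rundc3a at -1.35 to Tsix at 1.03.

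Within the renin-angiotensin system, Agt fell under the dye assignment used here and no other of the 20 detected members met the call. If the array titles name the pool in Cy5, Agt would be higher in the separated pool. Detection here rests on the planned rule, which removed nothing; above empty spots, only Atp6ap2 of the 20 was detected, and Agt was not. The values of the other members, Agt included, thus come from spots that did not clear the brighter empty ones on enough arrays. Agt was below 0 on all 10 arrays, with a mean of -1.31 on the arrays with the separated pool in Cy5 and -0.51 on the others. The mean of -1.31 includes 1 array at -2.49, where the others of that orientation lay between -1.05 and -0.97. Ctsa, the protease cathepsin A, was also below 0 on every array, at -0.49 ± 0.24, under the size limit. The median of the list was 0.03, with 10 members above and 10 below 0, at percentile 68.4 of random lists, and it changed sign under 8 of 29 alternatives. The angiotensin II receptor gene Agtr2 lay at 0.14 ± 0.55, the receptor-associated protein gene Agtrap at 0.30 ± 0.34 and renin (Ren1) at 0.16 ± 0.47. Ace, the angiotensin converting enzyme gene, lay at -0.22 ± 0.86. The prorenin receptor gene Atp6ap2 was at -0.05 ± 0.52, and the mineralocorticoid receptor gene Nr3c2 at 0.20 ± 0.46.

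Peptidases that form or degrade angiotensins also stayed outside the call. Enpep lay at 0.11 ± 0.59, Anpep at 0.09 ± 0.77, Lnpep at 0.14 ± 0.51 and Rnpep at -0.03 ± 0.26. Mme, the peptidase neprilysin, was at 0.21 ± 0.51, Thop1 at 0.26 ± 0.68, Prep at 0.27 ± 0.52, Prcp at -0.12 ± 0.49 and Dpp3 at -0.16 ± 0.85. Ctsd, the protease cathepsin D, was at -0.34 ± 0.98, and kininogen (Kng1) at -0.38 ± 0.54. The second spot of Agtrap lay at -0.19 and that of Rnpep at 0.09. Agt lost its call on the arrays with the separated pool in Cy3 alone, at -0.51, since that is under 1.5-fold.

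**Figure D2:**
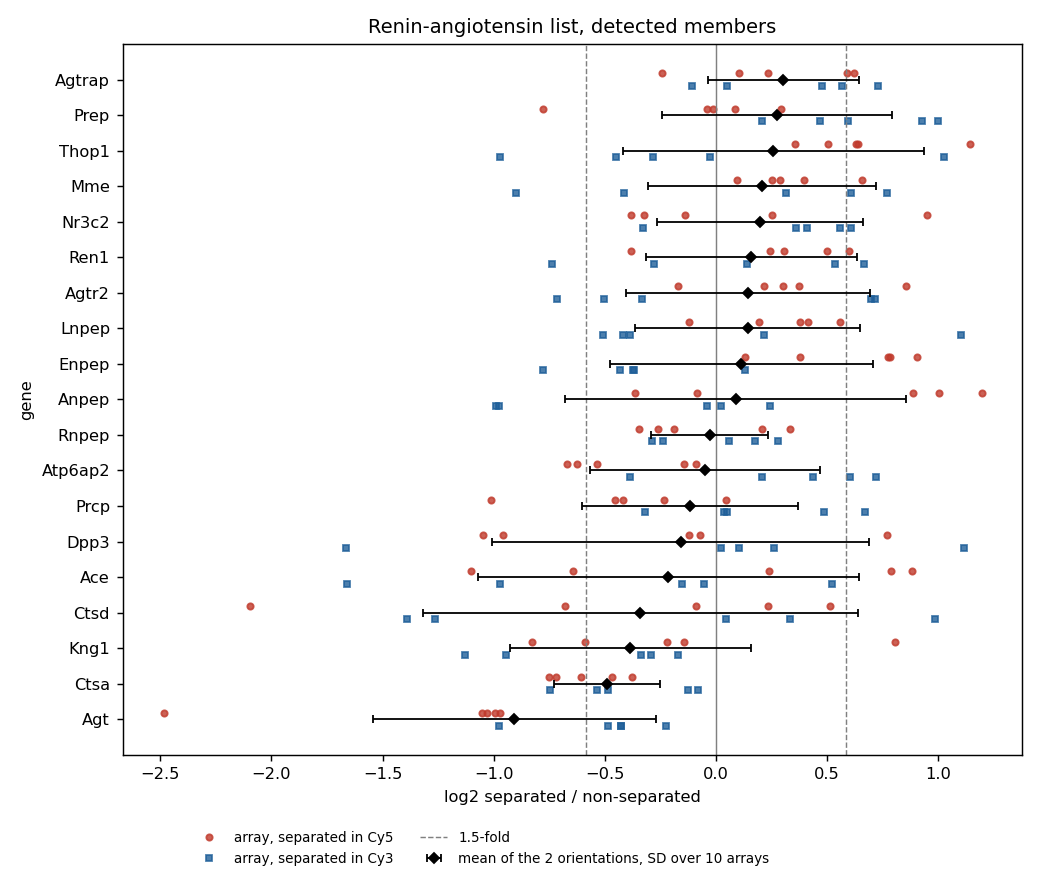
Log2 ratio of separated over non-separated (horizontal axis) for detected members of the renin-angiotensin list (vertical axis), drawn as circles (separated in Cy5), squares (separated in Cy3) and diamonds (mean, SD over 10 arrays), with 1.5-fold dashed. Agt, at -0.91, is the only member called, and Ctsa, at -0.49, the only other with one sign on every array.

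None of the 30 detected genes of the stress axis and PVN neuropeptide list was called. Crhr1, the receptor for corticotropin-releasing hormone, lay at -0.91 ± 0.70, beyond 1.5-fold but with 1 array above 0, from a dim spot. Avp, the vasopressin gene, was at -0.53 ± 0.49 with 9 of 10 arrays below 0. Crh, the releasing hormone gene, lay at 0.17 ± 0.54 from one of the dimmest spots. Oxt (oxytocin) was at -0.31 ± 0.92, and at -0.04 without replicate 3 of the arrays with the separated pool in Cy5. Trh (thyrotropin-releasing hormone) was at -0.13 ± 0.60 and the glucocorticoid receptor gene Nr3c1 at 0.05 ± 0.26. The list median was -0.08, at percentile 3.19, but it was above 0 in the authors' values (0.00) and with detection above empty spots (0.06, 6 members).

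Of 28 glucocorticoid-responsive genes, only Mt1 was called, and the list median was -0.04 at percentile 14.3. Above empty spots, 5 of the 28 were detected, and Mt1 was not among them. That median was 0.13 with the separated pool in Cy5 and -0.17 with it in Cy3. Known targets of the glucocorticoid receptor gave Fkbp5 0.16 ± 0.29, Sgk1 0.09 ± 0.40 and Tsc22d3 -0.04 ± 0.28. None of 29 immediate early genes, which mark recent neuronal activity, was called. Fos lay at -0.11 ± 0.67, Egr1 at -0.08 ± 0.47 and Nr4a1 at -0.23 ± 0.93, with a list median of -0.04 at percentile 18.4.

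Among lists of metabolism, cholesterol synthesis held 1 called gene, Hmgcs1, of 23 detected. Its median was 0.12 at percentile 98.1, with Insig1, a regulator of sterol sensing, at 0.38 ± 0.27 and Fdft1, which encodes squalene synthase, at 0.30 ± 0.28. Each of these 2 was above 0 on 9 of 10 arrays and neither was called. The list median was 0.01 with the separated pool in Cy5 and 0.25 with it in Cy3. The list of feeding and energy peptides had no called gene among 17, with a median of 0.14 at percentile 98.8. Taken array by array, that median was above 0 on 7 of 10 arrays. Only 2 of the 17, Cartpt and Socs3, were detected above empty spots. Igf1, a growth factor gene, lay at 0.39 ± 0.47, Cartpt, an appetite-suppressing peptide gene, at 0.22 ± 0.24 and Npy, an appetite-raising one, at -0.11 ± 0.63. The lowest member, Pomc, lay at -0.41 ± 1.12. Fasting metabolism had no called gene among 42, of which 8 were above empty spots, and a median of 0.00 at percentile 48.4.

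Astrocyte transcripts formed the group with the most calls. Of 27 detected members, 5 fell, among them Gjb6, Agt, Aldoc and Mt1, and none rose. Above empty spots, 13 members were detected, only Aldoc of the 5 kept its call and the list median was -0.05. With all members the list median was -0.20, below that of each of 10000 random lists, and it was below 0 on all 10 arrays. Ribosomal protein transcripts had the same median, -0.20, and -0.24 in the 36 members above empty spots, so this shift was not particular to astrocytes. Ndrg2, at -0.58 ± 0.34, Gja1, which encodes connexin 43, at -0.51 ± 0.22 and Sparcl1, at -0.31 ± 0.19, were below 0 on every array without meeting the size limit. Other markers spread around smaller values. The glutamate transporter genes Slc1a2 and Slc1a3 lay at -0.42 ± 0.65 and -0.02 ± 0.22, the filament gene Gfap at -0.20 ± 0.48 and the water channel gene Aqp4 at -0.10 ± 0.60. Fabp7, a fatty acid binding protein gene of radial glia and astrocytes, lay at 0.19 ± 0.15 and was above 0 on every array. Of the 27 astrocyte members, 1 is shared with the renin-angiotensin list and 4 with the glucocorticoid-responsive list. The glutamine synthetase gene Glul, chosen after its values were seen, had 9 spots with a median of -0.43, of which 6 were below 0 and 3 called lower, down to -0.99. Its brightest spot, which enters the list median, lay at 0.18 ± 0.74, with 0.87 in one orientation and -0.51 in the other, and was not called.

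Markers of other cells and regions gave no calls. Above empty spots, 6 microglial, 4 myelin, 2 vascular, 2 blood, 0 choroid plexus and 1 meningeal member were detected. Of the markers of neighbouring regions, 2 were. The absence of calls thus says little about the makeup of the punches. Microglial and immune genes had a median of 0.10 (27 detected, percentile 96.0), myelin and oligodendrocyte genes 0.04 (24, percentile 73.0) and vascular genes -0.07 (31, percentile 5.76). Taken array by array, the myelin median was below 0 on 8 of 10 arrays. Blood cell genes had a median of -0.01 (18, percentile 37.2), choroid plexus genes -0.01 (16, percentile 41.2) and meningeal genes 0.04 (23, percentile 78.7). Ptgds, a prostaglandin D synthase gene and the only meningeal member above empty spots, lay at -0.88 ± 0.54, below 0 on 9 of 10 arrays and not called. Markers of neighbouring brain regions had a median of 0.05 (22, percentile 82.1), Tcf7l2 above being one of them.

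Of 7 detected sex-linked genes, 2 were called. Tsix rose and Ddx3y fell, both on all 10 arrays, and the Tsix spot cannot be told from its overlapping partner Xist by its name alone. The Y-linked genes Eif2s3y and Uty lay at -0.21 ± 0.45 and 0.20 ± 0.66. Eif2s3y was below 0 on 9 of 10 arrays, and at -0.35 without the other, replicate 4 with the separated pool in Cy3. Their X-linked partners gave 0.16 ± 0.40 for Eif2s3x, 0.30 ± 0.72 for Kdm6a and -0.00 ± 0.54 for Ddx3x. The second spot of Kdm6a lay at -0.13. The median of the 7 detected members was 0.16, at percentile 96.0. Taken array by array, however, the list median was below 0 on 8 of 10 arrays. It was -0.18 with the separated pool in Cy5 and 0.07 with it in Cy3. The list joins Y-linked and X-linked genes, so its median does not describe a shared shift.

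**Figure D3:**
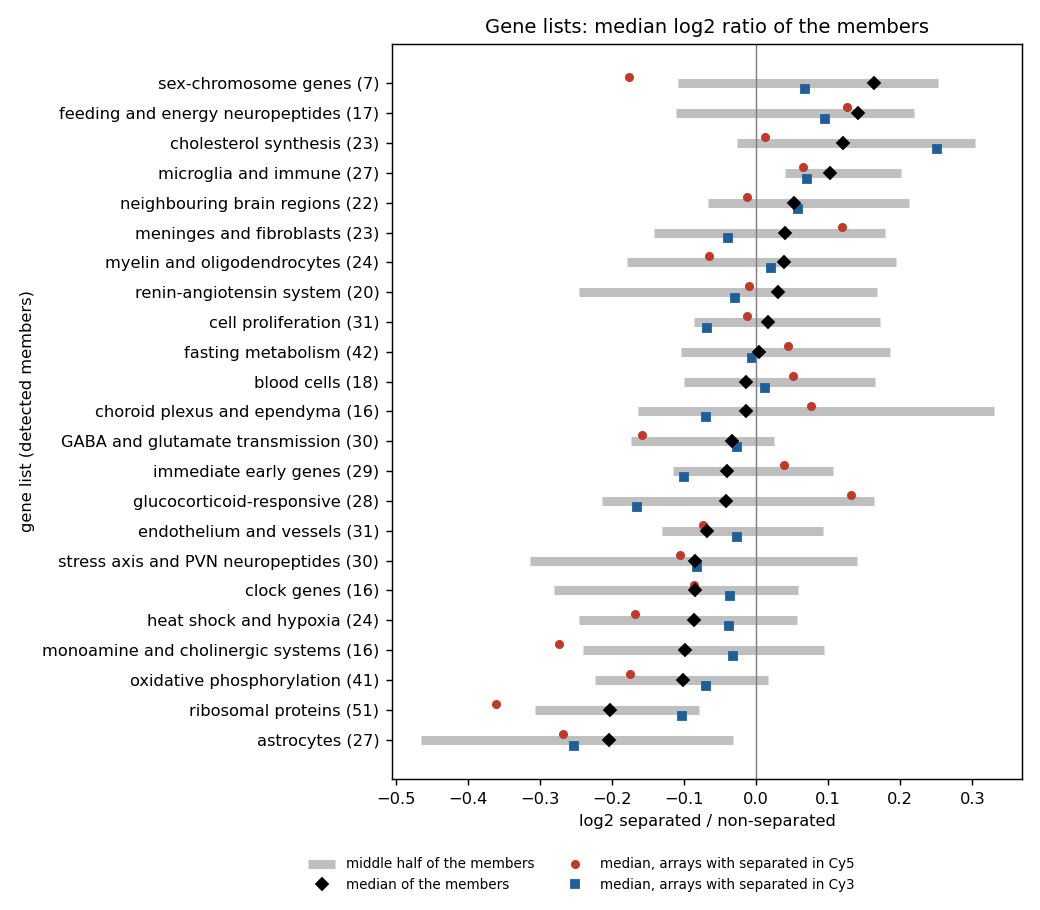
Median log2 ratio of separated over non-separated (horizontal axis) for the 23 gene lists (vertical axis, detected members in brackets). Diamonds are medians over all arrays, bars the middle range between quartiles of the members, circles and squares the medians with the separated pool in Cy5 and in Cy3. The astrocyte and ribosomal protein lists lie lowest, both at -0.20. Their orientation medians (Cy5, then Cy3) are -0.27 and -0.25 for astrocytes and -0.36 and -0.10 for ribosomal proteins.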

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

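The tests on ribosomal proteins were chosen after the result was seen, and those on astrocytes and sex-linked genes after their largest members were known but before the tested values. Values far from the other 4 arrays of a dye orientation were looked for in named genes, list medians and array measures, in 168 groups. Chance flags about 1 in 20 groups, which would be 8.40, and 14 stood apart.

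Array measures stood apart on 2 arrays with the number 3 and on 1 with the number 4. With the separated pool in Cy3, replicate 3 had a median log2 Cy5/Cy3 before normalization of 0.29, where the others lay between -1.17 and -0.79. The median Cy3 intensity of its empty spots was 105, against 150 to 161 on the others. Replicate 3 with the separated pool in Cy5 had a median log2 Cy5/Cy3 of -1.52, against -1.18 to -1.05. Replicate 4 with the separated pool in Cy3 had a spread of normalised log2 ratios (median absolute deviation) of 0.57, against 0.48 to 0.50.

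Single genes stood apart on 1 array each. Agt was at -2.49 on replicate 1 with the separated pool in Cy5, against -1.05 to -0.97, and Tsix on the same array at 1.44, against 0.84 to 1.01. Replicate 3 with the separated pool in Cy3 gave homeodomain interacting protein kinase 3 -0.92 (others -0.32 to -0.19) and Nr3c2 -0.33 (others 0.36 to 0.61). Oxt was at -2.39 on replicate 3 with the separated pool in Cy5, against -0.02 to 0.54. Eif2s3y was at 0.98 on replicate 4 with the separated pool in Cy3, against -0.55 to -0.18.

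List medians stood apart on 4 arrays. The stress axis list was at -0.28 on replicate 2 with the separated pool in Cy3, against -0.03 to 0.05. The fasting list was at -0.21 on replicate 4 with the separated pool in Cy5, against 0.02 to 0.09. The sex-chromosome list was at 0.29 on replicate 5 with the separated pool in Cy5, against -0.35 to -0.17, and at 0.82 on replicate 4 with the separated pool in Cy3, against -0.27 to -0.03.

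The number of calls under the real division of the arrays was larger than under the other divisions drawn. Only 1 of 100 splits of the 10 arrays into 5 and 5, the real one, gave as many as 29 called genes, and the highest other gave 10. For spots past adjusted p under 0.05 and 1.5-fold in limma, 1 of 100 splits, again the real one with 52, gave as many, and the highest other gave 1. These splits speak of array error between the 2 pools and not of separation. The real split also divides the 2 scan days, so the splits cannot tell a difference between the pools from a scan day effect.

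Lower astrocyte transcripts in the separated pool, with a list median of -0.20 that shrank to -0.05 in the 13 members above empty spots, were weighed against technical explanations. Their direction rests on the dye assignment used here and would reverse if the array titles name the pool in Cy5. A dye effect common to all arrays would leave the list at or above 0 in 1 orientation. However, the higher of the list's 2 orientation medians was -0.25. A scan day effect could lower both orientations, since each was scanned on its own day, so these medians cannot exclude it. Brightness would give random lists of like intensity medians as low, and the percentile of the list was 0. Fewer astrocytes in the separated punches may account for part of the pattern. The upper quartile of members lay below 0 at -0.0328, only just beyond its error of 0.0290. That value is not specific to cell number, since ribosomal proteins, which mark no cell type, had an upper quartile of -0.0788. Of the 13 astrocyte members above empty spots, Apoe, Glul, Fabp7, Sox9 and Vim lay above 0 and the others below. Among the latter, Slc1a3, at -0.02, and Slc6a11, at -0.05, were near 0. Only Aldoc, Ndrg2, Gja1 and Sparcl1 were below 0 on every array, and Fabp7 was above 0 on every array. Ribosomal protein transcripts had the same list median, -0.20, and -0.24 above empty spots. A difference between the pools in RNA quality or amplification may thus account for the lower astrocyte transcripts too and was not tested.

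The calls of Tsix and Ddx3y raise the possibility that more female animals stood behind the separated pool. If the array titles name the pool in Cy5, it would be the non-separated pool. More females in a pool would lower every Y-linked transcript there. However, the highest of the 3, Uty, lay at 0.20 with a standard error of 0.21. Its spot was dim, at percentile 21.4 of brightness over genes. Its mean was -0.18 with the separated pool in Cy5 and 0.58 with it in Cy3. Above empty spots, only Tsix of the 7 sex-linked genes was detected. Sex makeup thus may or may not explain the difference. Uty lay at 0.13 without replicate 3 of the arrays with the separated pool in Cy5 or without replicate 4 of the others, and at 0.32 without replicate 2 of the latter. Eif2s3y was below 0 on 9 of 10 arrays, at -0.21, and at -0.35 without replicate 4 of the arrays with the separated pool in Cy3. The sex of the animals behind each pool is not given in the sources used here, which keeps this open.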

How the results depend on the processing

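The detection rule based on empty spots was chosen after seeing the data, and all other alternatives were planned. By rule, a called gene had the same sign on every array. Its sign therefore could not change under other fold limits, sign rules or summaries over arrays. Nor could it change with an array left out or with either dye orientation alone. Only changes in background correction, normalization, detection, the spots read or the values used could alter it. Of the 23 called genes that fall under the naming rule, 22 kept their sign under each alternative that gave a value. The exception was Naa60, which lay at -0.14 when detection in both channels on all arrays was required and at -0.0483 in the authors' values; the second spot was read in the first case, and the cause was not tested in the other. The signs of 9 list medians held under all alternatives, among them astrocytes, ribosomal proteins, oxidative phosphorylation, cholesterol synthesis and feeding peptides, while 14 changed sign at least once.

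The main counts were 7 genes higher and 22 lower. A lower and a higher fold limit (2-fold) gave 33 and 1 higher and 95 and 2 lower, as their construction implies. Asking only that both orientation means share a sign gave 32 and 62. Print-tip loess gave 3 higher genes, and the mean over all spots of a gene 3 higher and 13 lower; the cause was not tested. Detection above empty spots left 1692 genes, with 3 higher and 4 lower, and moved the stress axis median from -0.08 to 0.0621. Arrays with the separated pool in Cy5 alone gave 511 and 387, and those with it in Cy3 alone 186 and 141. Dye effects do not cancel there and a sign need hold on 5 arrays only, and these causes were not separated. Leaving out 1 array at a time gave 6 to 16 higher and 24 to 31 lower genes, the 16 without replicate 1 of the arrays with the separated pool in Cy3; 5 to 7 of the main higher and 19 to 22 of the main lower genes remained. The stress axis median then ranged from -0.11 to -0.00 and the renin-angiotensin median from -0.02 to 0.08. The share of calls that were higher was 24.1%, and it ranged from 11.1% with print-tip loess to 56.9% with the separated pool in Cy5 alone. In the authors' values 7 and 22 genes were called, 3 and 18 of them the same.

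limma with a dye term called 5 higher and 22 lower genes, 4 and 17 of them among the main calls. With the replicate number as a block it called 1 and 1, Tsix and Rundc3a, but the numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.03 to 0.03, and 1 of 5 arrays correlated best with its own number.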

Other observations

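The tests on ribosomal proteins were chosen after the result was seen. Transcripts of the protein-making and respiratory machinery lay lower in the separated pool as groups, though no single member was called. Of 51 ribosomal protein genes, 45 were below 0, with a median of -0.20 that was lower than in each of 10000 random lists, and the median was below 0 on all 10 arrays. Rps14, at -0.44 ± 0.16, Rps24, at -0.36 ± 0.21, and Rpl5, at -0.32 ± 0.17, were below 0 on every array, while Rplp0 lay at 0.09 ± 0.15. Of 41 oxidative phosphorylation genes, 28 were below 0, with a median of -0.10 at percentile 0.16. The complex I gene Ndufa2, at -0.50 ± 0.11, and the complex III gene Uqcrh, at -0.41 ± 0.22, were below 0 on every array.

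Genes of amino acid transmission had a median of -0.03 (30 detected, percentile 17.7), with Gabbr1, a subunit of the metabotropic GABA receptor, at -0.40 ± 0.17 and below 0 on every array. Monoamine and cholinergic genes had a median of -0.10 (16, percentile 6.56) and clock genes -0.09 (16, percentile 7.49). Proliferation genes had a median of 0.02 (31, percentile 56.1) and heat shock and hypoxia genes -0.09 (24, percentile 3.34). None of these lists held a called gene. Above empty spots, 7 amino acid transmission, 0 monoamine and cholinergic, 1 clock, 10 proliferation and 7 heat shock members were detected. Hbb-b1, an adult haemoglobin gene that marks blood, lay at 0.45 ± 0.16 and above 0 on every array. Mbp, the myelin basic protein gene, lay at -0.43 ± 0.27 and Fasn, fatty acid synthase, at -0.25 ± 0.13, both below 0 on every array.

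Lower ribosomal protein transcripts were weighed as a hypothesis. A dye effect common to all arrays would bring 1 orientation to 0 or above. However, the higher of the 2 orientation medians was -0.10, beyond its SD of 0.06. The other was -0.36, so the size of the shift depended on the orientation. Brightness alone would give random lists of like intensity as low a median, and the percentile of the list was 0. A difference between the pools in RNA quality or amplification may still account for the shift, as may scan day or separation itself. With 1 pool per group and 1 orientation per scan day, these cannot be told apart.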
